A study of Xenopus laevis with 4 samples.

How the data were processed

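The series compares RNA from manually isolated vegetal cortices with RNA from whole stage VI oocytes of Xenopus laevis on 4 Affymetrix Xenopus arrays, 2 per group. Per the labels, collagenase-treated oocytes were bisected, yolky cytoplasm was pressed away from the vegetal pieces, and the cortices were collected in batches, with intact oocytes of the same female as controls. Per the labels' protocols, total RNA was DNase-treated, amplified in 2 cycles of cDNA synthesis and labelled with biotin in a 1-colour design. Each sample carries its group and replicate number in its title. The description of vegetal cortex replicate 2 repeats the sample and replicate numbers of vegetal cortex replicate 1, and its title was followed.

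The deposited values are intensity values on a linear scale, 1 per probe set and array, made with MAS5 per the submitters' processing notes; the MAS5 version and settings are not given in the sources used here. MAS5 combines the perfect-match and mismatch probes of a probe set into 1 signal and scales each array by a trimmed mean. In the deposited table the mean over all probe sets after trimming 2% at each end was 1500.1 on both whole oocyte arrays and 1500.2 on both cortex arrays, so the values were used with this scaling. Because each array is scaled to the same mean, a change is relative to the other RNAs of the same sample and not an amount per oocyte or per cortex. MAS5 detection calls were not used here, so no probe set is called present or absent. MAS5 signals of dim probe sets are noisy, and amplification in 2 cycles favours the 3' ends of transcripts.

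The table holds 15611 probe sets, of which 120 are controls and 15491 are not. Gene names came from the platform annotation, with symbols updated through gene identifiers from an annotation of the Xenopus_laevis_v10.1 assembly. A single symbol was given for 9304 probe sets, several for 195 and none for 5992. Of the probe sets with 1 symbol, 9227 had an identifier found in the gene table, and 2 symbols were updated. No gene was named from a probe set with several symbols. The endings .L and .S mark the homeologous copies on the long and short subgenomes of this allotetraploid frog, and were treated as separate genes.

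An offset of 19.11, the 10th percentile of all non-control signals, was added before log2, so fold changes of dim probe sets are understated. Probe sets with a mean signal of at least 271.5, the 40th percentile, were tested, which left 9295. Vegetal cortex was compared with whole oocytes by limma (lmFit, and eBayes with an intensity trend; 2 residual and 6.22 prior degrees of freedom), two-sided, without a block, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. A test against a 2-fold bound (limma treat) used the same values. The number of probe sets at least 4-fold, or at least 2-fold, different in both same-numbered pairs was counted, with the same count for replicate 1 against replicate 2 as a yardstick. Gene lists were tested with limma camera at a preset correlation of 0.01 on the brightest tested probe set of each of 5231 symbols, with Benjamini-Hochberg adjustment over the 11 lists with at least 3 tested genes. With a correlation estimated per list, camera has only 2 degrees of freedom here, which limits how small its p can be. The estimate was 0.208 for germ plasm, 0.581 for the followed genes and 0.836 for the egg envelope, and at most 0.085 for the other lists. Where it lies well above the preset of 0.01, the p-values at the preset can be too small. All adjusted p-values in the text are limma's unless another test is named. Errors of signals are SD over n = 2 arrays, and errors of log2 changes are limma's SE.

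The groups, the main test, 15 gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The lists covered germ plasm RNAs, other RNAs of the vegetal cortex, the genes the study followed, animal hemisphere RNAs, nuclear and mitochondrial genes of the respiratory chain, ribosomal proteins, the cytoskeleton, RNA localization and storage factors, cell cycle and maturation, Wnt and TGF-beta signalling, the egg envelope, and markers of follicle and stromal cells, of blood, and of yolk precursors and liver. No probe set here carried a single symbol of the mitochondrial genome list, nor of spire1, sybu, velo1, foxi2, prkca or trim33, which were not analysed here. The text names the 12 called probe sets with the largest increase and up to 10 with the largest decrease, with 1 symbol each and the same direction in both pairs. Where too few decreases passed, probe sets were ranked by the smaller change of both pairs and are said not to have passed. It also names the tested members of the germ plasm, vegetal cortex, followed and animal lists, up to 4 members of each other list (called members, or the brightest), and up to 5 probe sets without a single symbol in each direction, given by their values and not by their identifiers.

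Each replicate came from its own female and, per the labels, the control oocytes came from the same female as the cortices, so the same-numbered samples were taken as pairs. As a check across probe sets, which are not independent, the replicate differences of the cortex arrays and of the whole oocyte arrays had a correlation of 0.35. No other batch is given by the labels. The replicate number is therefore both donor and any processing batch, and both pairs' values are given beside the main results.

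The test was checked on 5 simulations of 9295 probe sets, each with 200 changed. It recovered 2% of simulated 2-fold increases, 22% of 2.83-fold increases, 60% of 4-fold increases, 97% of 8-fold increases and 100% of 16-fold increases. For decreases of these sizes it recovered 2%, 14%, 59%, 96% and 97%, and 3.68% of all calls were false. The simulated arrays had the same error in both groups and no difference between females. In the data the cortex arrays varied more and replicate differences were correlated between groups, so these rates hold for the simulated setting only. Alternatives were other offsets (none, or the 25th percentile), other filters (none, or the 60th percentile), quantile normalization, median centring, eBayes without the trend or robust, the replicate number as a block, removal of probe sets that can hybridize to several transcripts, crossed pairs, other camera settings and leaving out each array in turn. A group with 1 array left was assumed to vary like the other group. The cortex arrays differed more from each other than the whole oocyte arrays did, so this can understate the error of a lone cortex array. The number of arrays limits the precision of every value. Values were computed with R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.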

Results

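The vegetal cortex is the thin layer of cytoplasm and cytoskeleton under the plasma membrane of the lower, yolk-rich hemisphere of the frog oocyte. It anchors maternal RNAs that later act in germ cell formation and in embryonic patterning, and the comparison asks which RNAs are concentrated there. RNA from isolated vegetal cortices and from whole stage VI oocytes was measured on Affymetrix arrays, with 2 arrays per group and a different female behind each replicate. The median signal over all probe sets was 593.9 and 546.0 in whole oocyte replicates 1 and 2, and 555.0 and 513.5 in vegetal cortex replicates 1 and 2. Across probe sets, which are not independent replicates, log2 signals correlated at 0.96 between the whole oocyte arrays and at 0.92 between the cortex arrays.

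Most tested genes of the known germ plasm RNAs (13 of 14) and of the other known vegetally anchored RNAs (6 of 7) were higher in the vegetal cortex. As groups both lists passed limma camera at its preset correlation and not with an estimated correlation (adjusted p = 0.135 and 0.126). nanos1.L, a translational repressor needed by germ cells, was 16.7-fold higher in the cortex (log2 change 4.06 ± 0.32 SE, adjusted p = 0.00143), and trim36.L, a ubiquitin ligase of the vegetal cortex, was 25.2-fold higher (4.65 ± 0.38, adjusted p = 0.00143). Both were higher in both females. Among 9295 tested probe sets, 308 were higher in the cortex and 0 were lower by limma at an adjusted p under 0.05, against 745 higher and 429 lower at an unadjusted p under 0.05. The 308 calls, 3.31% of those tested, were higher in both pairs and had a median increase of 5.71-fold. They included 170 probe sets with a single symbol, which stood for 152 genes. At least a 4-fold increase in both females was seen for 195 probe sets and a 4-fold decrease in both for 0, where replicate 1 exceeded replicate 2 by as much in both groups for 4 probe sets and the reverse held for 0. A test against a 2-fold bound kept 81 increases and 0 decreases. With the replicate number as a block, 355 increases and 0 decreases were called, against 885 higher and 890 lower at an unadjusted p under 0.05. The counts depended on single arrays: without whole oocyte replicate 1 there were 125 increases (11 against the 2-fold bound), without whole oocyte replicate 2 there were 140 (23), without vegetal cortex replicate 1 there were 697 increases (196) and 673 decreases (79), and without vegetal cortex replicate 2 there were 666 increases (284) and 38 decreases (0). In the fits with a single cortex array left, the error came from the whole oocyte arrays, which varied less, so these counts can be too high. The 2-fold bound gave 21 increases with no filter on dim probe sets and 35 without the intensity trend.

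**Figure D1:**
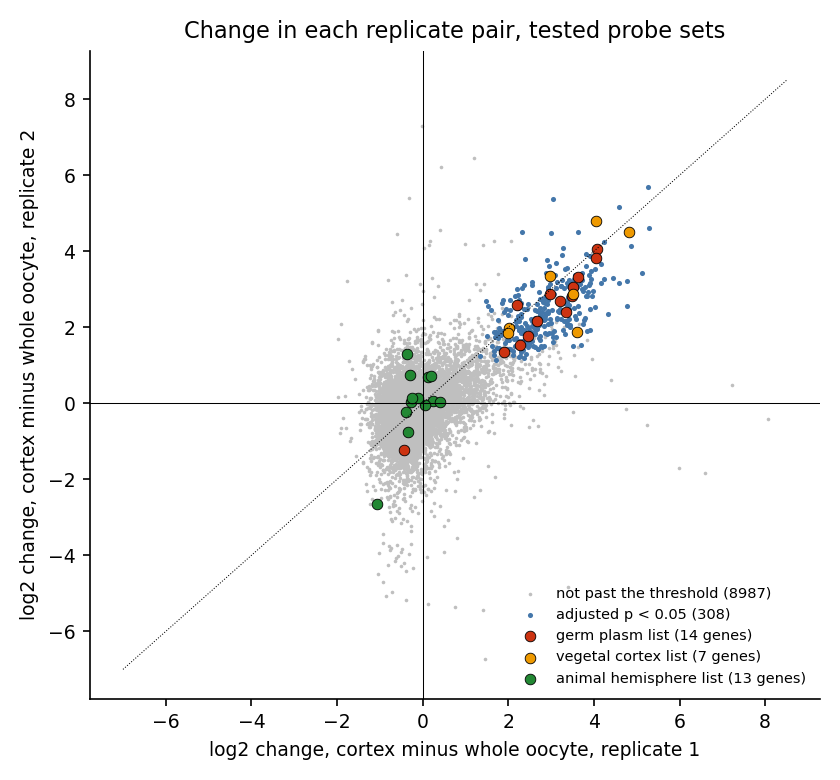
Log2 change from whole oocyte to vegetal cortex for each of 9295 tested probe sets, in the pair of replicate 1 (horizontal axis) and the pair of replicate 2 (vertical axis), with the 308 called probe sets in blue and listed genes as outlined points. The called probe sets lie in the upper right, higher in the cortex in both pairs, together with 13 of 14 germ plasm genes, while the animal hemisphere genes other than dand5.S lie nearer to 0 than these 13.

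Germ plasm is the store of mitochondria, RNA and protein that is inherited by the future germ cells. Of 14 tested genes known from it, 13 rose in the vegetal cortex, and the same number rose when adjusted over the list alone. The list's median log2 change was 2.90 (3.09 in the first pair and 2.64 in the second), against -0.20 for all tested probe sets. After nanos1.L, the largest changes were those of germes.L (15.3-fold, log2 change 3.93 ± 0.31) and grip2.L, a scaffold protein of the germ plasm (11.2-fold, 3.48 ± 0.30). ddx25.L, an RNA helicase, rose from a signal of 4090 ± 1009 to 39487 ± 1450 (SD, n = 2), and the germ cell RNA-binding protein gene dazl.L rose from 5359 ± 1530 to 40810 ± 1708. wnt11b.L, a secreted Wnt ligand, rose 8.91-fold, otx1.L 7.60-fold, pgat.L 7.33-fold and dnd1.L, an RNA-binding protein of germ cells, 5.35-fold. Both homeologs of plin2, a coat protein of lipid droplets, rose (5.25-fold for plin2.S and 4.35-fold for plin2.L). Both homeologs of the RNA-binding protein gene rbpms2 also rose (3.75-fold for rbpms2.L and 3.07-fold for rbpms2.S). tdrd6.L, a Tudor domain protein gene, had a log2 change of -0.84 ± 0.37 (adjusted p = 0.402). The list stood above other genes by limma camera (adjusted p = 2.96e-28), with an adjusted p = 0.135 with an estimated correlation. plin2.L no longer passed without whole oocyte replicate 1 (log2 change 1.66), and both rbpms2 homeologs no longer passed without whole oocyte replicate 1 (1.91 for rbpms2.L and 1.55 for rbpms2.S), without whole oocyte replicate 2 (1.90 and 1.68), with no filter on dim probe sets or without the intensity trend.

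**Figure D2:**
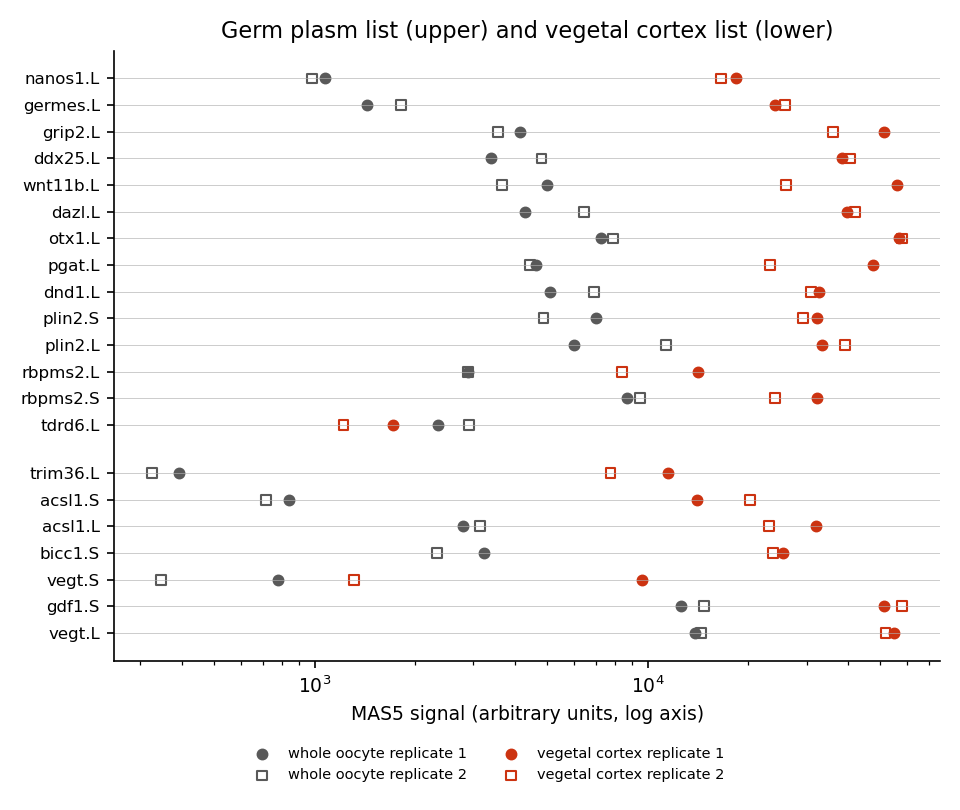
MAS5 signal (log axis) of each tested gene of the germ plasm and vegetal cortex lists on the 4 arrays, with whole oocytes in grey and vegetal cortices in red, filled circles for replicate 1 and open squares for replicate 2. Both cortex arrays lie above both whole oocyte arrays for 20 genes, and below them for tdrd6.L.

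Other RNAs known to be anchored at the vegetal cortex rose as well. Of 7 tested genes, 6 rose, and 7 rose when adjusted over the list alone; the median log2 change was 3.15 (3.52 in the first pair and 2.87 in the second). Besides trim36.L, both homeologs of acsl1, a long-chain acyl-CoA synthetase, were among them, at 21.3-fold for acsl1.S (log2 change 4.42 ± 0.35) and 9.14-fold for acsl1.L (3.19 ± 0.31). bicc1.S, an RNA-binding protein gene, rose 8.90-fold. gdf1.S, which encodes the TGF-beta ligand Vg1, rose 3.99-fold, from 13701 ± 1520 to 54687 ± 4774, and vegt.L, a T-box factor that specifies endoderm, rose 3.77-fold, from 14146 ± 430 to 53448 ± 2303 (SD, n = 2). vegt.S had a log2 change of 2.73 ± 0.83 (adjusted p = 0.185), with 3.59 in the first pair and 1.87 in the second, and passed with the replicate number as a block (adjusted p = 0.036) or without vegetal cortex replicate 2 (log2 change 4.16). The list stood above other genes by camera (adjusted p = 1.74e-18), with an adjusted p = 0.126 with an estimated correlation.

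The reticulon gene rtn3.L and the exonuclease domain gene exd2.S, which the study followed further, rose 9.03-fold and 6.81-fold. The other homeolog, exd2.L, had a log2 change of -0.76 ± 0.34 (adjusted p = 0.402). These genes were picked by the study from these samples, so the count of 2 of 3, which was also 2 when adjusted over the list alone, and the camera result (adjusted p = 0.002, and adjusted p = 0.321 with an estimated correlation) are not independent evidence of their direction.

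Several of the largest increases lay outside these lists. timm8b.S, a chaperone gene of the mitochondrial intermembrane space, rose from a signal of 296.5 ± 117.5 to 9415 ± 534 (31.0-fold, log2 change 4.95 ± 0.40, adjusted p = 0.00143). efnb1.L, an ephrin ligand gene, rose 19.0-fold (4.25 ± 0.37) and dsc3.S, a desmosomal cadherin gene, 16.8-fold (4.07 ± 0.52). Transcription factor genes were present too. six3.L was 12.1-fold higher (3.60 ± 0.42), and tfcp2l1.L rose from a dim signal of 44.1 ± 5.5 to 967.3 ± 2.6 (SD, n = 2), with a log2 change that depends on the offset (3.97 ± 0.49, 4.46 without an offset and 3.08 with the 25th percentile). The brighter homeolog tfcp2l1.S went from a mean signal of 2228 to 5422 (log2 change 1.21, adjusted p = 0.2285). pced1a.L rose 12.8-fold and acsbg2.L, another acyl-CoA synthetase gene, 11.9-fold. camk2g.S, a subunit of calcium/calmodulin-dependent kinase II, was represented by 20 tested probe sets, of which 13 were called and all had log2 changes between 2.25 and 3.78. Of these 20, 19 can hybridize to several transcripts, and the highest of them no longer passed without whole oocyte replicate 2 (log2 change 3.14). A further 138 called probe sets had no single symbol. Among them the largest increases with the offset used here were 44.3-fold, 29.3-fold, 22.6-fold and 19.4-fold. The next rose from a signal of 21.1 ± 16.2, near the offset itself, to 792.2 ± 540.8, so that its log2 change of 4.21 has no firm size (5.29 without an offset and 2.97 with the 25th percentile), and it no longer passed without whole oocyte replicate 2 (3.79).

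No gene known from the animal hemisphere passed the test. Of 13 tested genes, 0 rose and 0 fell by limma, also when adjusted over the list alone. The median log2 change was 0.01 and the mean -0.07, and camera placed the list on the higher side of all genes (adjusted p = 0.425). dand5.S, a secreted antagonist of TGF-beta ligands, had the lowest value, -1.86 ± 0.68 (adjusted p = 0.316), with -1.07 in the first pair and -2.65 in the second. sox3.S, a transcription factor gene, had a log2 change of 0.40 ± 0.30, sox3.L of 0.46 ± 0.60 and gnb1.S of 0.45 ± 0.36, while zfand4.L had signals of 10609 ± 211 and 10611 ± 238 in whole oocytes and cortices (SD, n = 2). The changes of zfand4.S, ddx3x.L, pabpc1.L, pabpc1.S, ets2.L, zic2.L and zic2.S lay between -0.30 and 0.23. Without vegetal cortex replicate 1, dand5.S passed as lower (log2 change -3.02).

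No probe set passed as lower, although 65.6% of tested probe sets had a log2 change below 0. At least a 2-fold decrease in both pairs was seen for 51 probe sets, beside 521 with at least a 2-fold increase, where replicate 1 exceeded replicate 2 by as much in both groups for 145 probe sets and the reverse held for 47. Ranked by the smaller decrease of the pairs, the 10 named genes, none of which passed, began with the nuclear receptor gene ppard.S, the receptor gene fgfr4.L, the kinase gene plk2.S and the nucleoporin gene nup214.L, which with dnai4.S and the mitochondrial carrier gene slc25a24.S had log2 changes between -1.93 and -1.48. The others were mrpl15.L, a mitochondrial ribosomal protein gene (-1.51 ± 0.40, adjusted p = 0.112), pcif1.S (-1.24 ± 0.33, adjusted p = 0.12), nolc1.L, a nucleolar protein gene (-1.33 ± 0.33, adjusted p = 0.0918), and stk3.S, a kinase of the Hippo pathway (-1.51 ± 0.39, adjusted p = 0.102). The 5 probe sets without a single symbol that ranked lowest by this rule had log2 changes of -1.47, -1.47, -1.56, -1.36 and -1.67. All of these named genes and probe sets passed as lower without vegetal cortex replicate 1, between -1.29 for pcif1.S and -3.14 for slc25a24.S, and 3 of the probe sets without a single symbol also did without vegetal cortex replicate 2 (-1.49, -1.47 and -1.45).

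Nuclear-encoded genes of the respiratory chain passed as slightly lower in the cortex by camera at the preset correlation (adjusted p = 0.00591), and not with an estimated correlation (adjusted p = 0.225). Of 66 tested genes, 0 rose and 0 fell on their own, also when adjusted over the list alone, and 8 had a log2 change above 0. The median was -0.45 (-0.41 and -0.47 in the pairs), which is -0.25 relative to all tested probe sets. Among its brightest members, the ATP synthase genes atp5f1a.L, atp5f1b.S and atp5mc3.S had log2 changes of -0.55 ± 0.36, -0.28 ± 0.28 and -0.32 ± 0.27, and uqcrc1.L of complex III -0.41 ± 0.42. atp5f1a.L also belongs to the animal list, and passed as lower without vegetal cortex replicate 1 (-1.01). Without vegetal cortex replicate 2 the list had an adjusted p = 0.0552.

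The ribosomal, cell cycle and cytoskeletal lists showed no called member. All 70 tested ribosomal protein genes, 43 cell cycle and maturation genes and 29 cytoskeletal genes missed the threshold, also when adjusted over each list alone. The members named here are the brightest of each list, and others lay further from 0. Log2 changes ranged from -1.35 to 0.225 for ribosomal proteins, from -1.62 to 0.50 for maturation genes and from -0.70 to 1.74 for cytoskeletal genes. The ribosomal proteins had a median log2 change of -0.22, beside -0.20 for all tested probe sets (camera adjusted p = 0.122), with rpl35a.S, rps18.L and rpl15.L between -0.06 and -0.02 and rplp0.S at -0.74 ± 0.27. The maturation genes had a median of -0.19 (adjusted p = 0.182), and the cyclin genes ccnb1.S, ccnb2.L, ccnb2.S and ccna1.S had changes of 0.05, -0.02, -0.03 and -0.25. Both lists passed as lower with quantile normalization (adjusted p = 0.00616 for ribosomal proteins and 0.000142 for the maturation genes), with no filter on dim probe sets (0.0226 and 0.0281) and without vegetal cortex replicate 2 (0.0176 and 0.0474). Cytoskeletal genes had a median of -0.09 and a mean of 0.04, and camera placed them on the higher side (adjusted p = 0.4); actg1.L was at -0.60 ± 0.32, actb.L at -0.16 ± 0.34, tubb4b.L at -0.10 ± 0.27 and tubb4b.S at -0.54 ± 0.32. actg1.L passed as lower without vegetal cortex replicate 1 (-0.98).

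Among factors of RNA localization and storage 1 gene was called, and the list passed camera as higher at the preset correlation (adjusted p = 0.00261) and not with an estimated correlation (adjusted p = 0.321). lsm14b.L, which encodes a protein of stored oocyte messenger ribonucleoprotein particles, rose 6.37-fold, from a signal of 4747 ± 20 to 30517 ± 4902 (SD, n = 2; log2 change 2.67 ± 0.29, adjusted p = 0.00301). Of 17 tested genes 1 rose, and 4 rose when adjusted over the list alone; the other 3 were celf1.L (1.68 ± 0.39), ddx6.L (1.65 ± 0.49) and lsm14b.S (1.30 ± 0.32). The list's median was 0.16 (-0.05 and 0.24 in the pairs), with 10 of the 17 genes above 0. The list also passed camera on ranks (adjusted p = 0.00724), and how much these few members carry its result was not tested.

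Among 22 tested genes of Wnt and TGF-beta signalling, acvr1.L, a type I receptor of bone morphogenetic proteins, was the 1 gene that rose (5.44-fold, log2 change 2.44 ± 0.35, adjusted p = 0.00879), also when adjusted over the list alone. It no longer passed without whole oocyte replicate 1 (log2 change 2.1), and its list did not pass (median 0.07, camera adjusted p = 0.123). The other homeolog, acvr1.S, had a log2 change of 0.53 (adjusted p = 0.501), and the difference between the copies did not pass by limma (adjusted p = 0.0676). The 4 tested genes of the egg envelope, a coat secreted by the oocyte, had a median of 0.50 (camera adjusted p = 0.0144, and adjusted p = 0.394 with an estimated correlation). None rose over all tested probe sets by limma, and 1 rose when adjusted over the list alone, zp2.L (log2 change 1.48 ± 0.37, adjusted p = 0.0892 over all); zp4.S was at 0.64 ± 0.32, zpd.L at 0.35 ± 0.39 and zpax.L at 0.21 ± 0.56. zp2.L passed with the higher signal limit (adjusted p = 0.0492) and without vegetal cortex replicate 2 (log2 change 1.95). The list did not pass without whole oocyte replicate 2 (adjusted p = 0.111) or without vegetal cortex replicate 1 (adjusted p = 0.584), where zpd.L and zpax.L had values of -0.20 and -0.57.

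**Figure D3:**
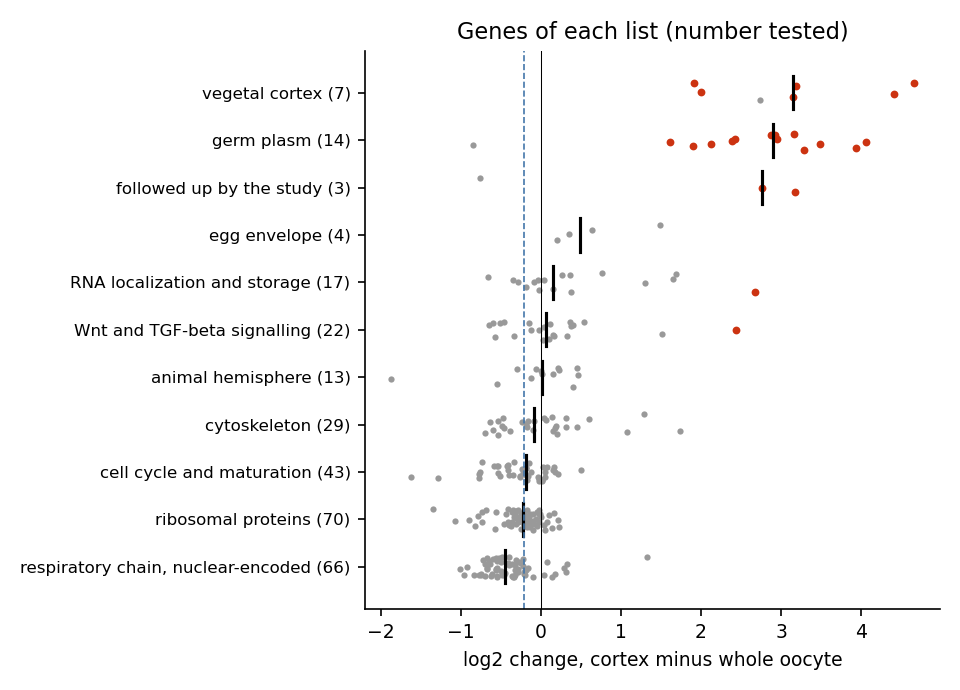
Log2 change from whole oocyte to vegetal cortex (horizontal axis) of each tested gene in 11 lists, with called genes in red, others in grey, the list's median as a black bar and the median of all tested probe sets as a dashed line at -0.20. The medians of the vegetal cortex list (3.15), the germ plasm list (2.90) and the genes followed by the study (2.77) lie far to the right of the other lists, which lie between -0.45 and 0.50.

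Markers of other cell types were mostly too dim to test. Of 17 listed genes of follicle and stromal cells on the array 2 were tested, and cyp17a1.L, a steroid hydroxylase gene, rose 4.39-fold, from a signal of 5034 ± 1198 to 22708 ± 8705 (SD, n = 2; log2 change 2.13 ± 0.36, adjusted p = 0.0168), also when adjusted over the list alone; it no longer passed without whole oocyte replicate 1 (1.89). fn1.S, fibronectin, had a log2 change of 0.15 ± 0.30. Both genes were already bright in whole oocytes (5034 for cyp17a1.L and 13857 for fn1.S), while the other listed genes did not reach the signal limit. The rise of cyp17a1.L alone therefore does not show that follicle cells were enriched with the cortices. Of 16 blood genes and 10 yolk precursor and liver genes, 1 each was tested, slc4a1.L (-0.11 ± 0.48) and serpina1.S (0.30 ± 0.52).

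Control probe sets differed between arrays. The log2 ratio of the 3' to the middle probe set of beta-actin was -0.31 and 1.4 in whole oocyte replicates 1 and 2 and -0.30 and 2.79 in vegetal cortex replicates 1 and 2, and that of Gapd was 1.17, 1.05, 1.31 and 1.72. The spiked poly-A controls were on average 8.0-fold brighter on the replicate 1 arrays than on the replicate 2 arrays. Their mean log2 signals were 10.82 and 6.97 in whole oocyte replicates 1 and 2, and 10.71 and 8.57 in vegetal cortex replicates 1 and 2. Replicate 1 minus replicate 2 had an SD over probe sets of 0.53 log2 units in whole oocytes and 0.88 in cortices, and 168 tested probe sets were at least 4-fold lower in vegetal cortex replicate 2 than in replicate 1, beside 80 the other way and 19 in either direction between the whole oocyte arrays.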

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

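The values given on a difference between females, on between-array scaling and on stromal cells as a source of cyp17a1 were chosen after those results were seen. The other tests in this part were chosen before.

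Some control probe sets, which enter no comparison of the report, separated the groups. The hybridization controls were brighter on both cortex arrays than on both whole oocyte arrays, by 0.66 log2 units on average (11.97 and 12.58 against 11.54 and 11.69). The log2 ratio of 3' to middle probe set of Gapd was also higher on both cortex arrays, by 0.41 on average, while its log2 ratio of 3' to extreme 5' probe set did not separate the groups (5.01 and 4.29 in whole oocytes, 4.54 and 4.81 in cortices).

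The vegetal cortex arrays differed from each other more than the whole oocyte arrays did, with an SD ratio of 1.66 over tested probe sets. Noise of low signals is argued against, since the ratio was 1.71 (95% bootstrap interval 1.60 to 1.84) among the 3099 brightest probe sets. Intervals in this paragraph resample probe sets, or genes for the intraclass correlation, which are not independent. They do not measure how cortex preparations vary. A difference between the females shared by the whole oocyte is taken to enter both groups alike. The variance between the whole oocyte arrays, the most it can hold, was 36.1% of the cortex variance (95% bootstrap interval 33.8 to 38.6). This share restates the SD ratio, so it is no separate test of this cause. Effects at the level of single probe sets, such as uneven amplification, cannot be told apart from differences in the RNA: probe sets of 1 gene shared the cortex difference with an intraclass correlation of 0.3 (0.22 to 0.37), an interval that holds the bound set for such effects, beside 0.30 for the whole oocyte difference and 0.65 for the change from whole oocyte to cortex. How each dissection went, and differences between the females restricted to the cortex, may contribute and were not tested. Vegetal cortex replicate 2 also had the highest log2 ratios of 3' to middle probe set, for beta-actin (2.79, beside -0.30 in vegetal cortex replicate 1) and for Gapd (1.72, beside 1.31). Its Gapd ratio of 3' to extreme 5' probe set was not the highest (4.81). Whether these ratios relate to the spread was not tested.

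The probe sets past the threshold lay higher in the cortex, with 308 higher and 0 lower. At an unadjusted p under 0.05 there were 745 higher and 429 lower in the main fit. With the replicate block there were 885 higher and 890 lower, so the imbalance was not seen at that threshold. For between-array scaling in the sense of different distributions of signals, quantile normalization gave 325 higher calls and 1 lower call. It moved 7600 probe sets up and 1695 down. Of the 429 lower at an unadjusted p under 0.05 in the main fit, it moved 361 up and 68 further down. For most of these it pushed away from a lower call, so it does not decide this cause. A uniform shift of the cortex arrays stays open as well. Median centring moved every probe set up, so its 346 higher and 0 lower calls do not test this. Scaling each array on its hybridization controls moved the median log2 change to -0.86 and gave 0 higher and 0 lower calls by limma (309 and 2514 at an unadjusted p under 0.05), and does not decide it either, because the controls also follow the amount of labelled RNA on an array and differed between the cortex arrays. The spread brought by vegetal cortex replicate 2 is argued against as the whole cause, since 666 higher and 38 lower calls were made without it, but a part remains possible, because lower calls appeared then and 673 appeared without vegetal cortex replicate 1. The simulated recovery was 60% for 4-fold increases and 59% for 4-fold decreases, and 22% for 2.83-fold increases and 14% for 2.83-fold decreases. The simulation drew both directions with the same error, so it cannot show whether decreases are harder to recover in these data. Whether few RNAs are kept out of the vegetal cortex was not tested apart from these.

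cyp17a1.L was 4.39-fold higher in the cortex. Follicle or stromal cells left on the isolated cortices cannot be told apart from RNA of the oocyte itself: of 14 probe sets of collagen, sparc, acta2 and tagln, 0 reached the signal of 271.5 required for testing, and the highest cortex mean among them was 159.2. On both cortex arrays 4 of them were higher than on both whole oocyte arrays, among them col1a2.L (24.1 and 14.5 in whole oocytes, 82.7 and 71.1 in cortices) and tagln.S (86.4 and 65.0, 125.1 and 193.3), and 1 was lower. Signals this close to the floor do not set the share of such cells.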

How the results depend on the processing

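All alternatives in this part were fixed before the data were examined. Of 37 named probe sets that were called, 33 had a value under every alternative that used all arrays, and 31 of these kept the call throughout; the exceptions were both rbpms2 homeologs, which missed the threshold with no filter and without the trend. Of the rest, 2 (tfcp2l1.L and 1 probe set without a single symbol) fell under the higher signal limit and 2 (camk2g.S and 1 without a single symbol) were removed with the probe sets that can hybridize to several transcripts; they kept the call under the other alternatives that used all arrays. None of the 37 changed direction where it had a value. Without whole oocyte replicate 1, 5 of them no longer passed, and without whole oocyte replicate 2, 4 did not. Of 52 named probe sets that were not called, 18 passed without vegetal cortex replicate 1 and 5 without vegetal cortex replicate 2. Fewer arrays and the assumption that a lone array varies like the other group enter these fits; the causes of the other shifts were not tested. With the replicate block 355 probe sets were higher and 0 lower, 300 of them shared with the 308, and the block changed no other named call than that of vegt.S and no list's call. Dim probe sets limit what can be seen: signals under 271.5 were not tested.

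Leaving out 1 array gave 125 to 697 higher and 0 to 673 lower probe sets, and 11 to 284 higher and 0 to 79 lower against the 2-fold bound. With quantile normalization 1 probe set was lower. Against the 2-fold bound 21 were higher with no filter and 35 without the trend. At least 2-fold lower in both pairs were 30 with the 25th percentile as offset, 118 with no filter, 22 with the 60th percentile as filter and 20 with median centring.

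Camera with an estimated correlation gave an adjusted p of 0.135 for germ plasm, 0.126 for the vegetal cortex list, 0.321 for the followed genes and for localization factors, 0.225 for the respiratory chain and 0.394 for the egg envelope, and camera on ranks 0.346 for the followed genes. Quantile normalization gave 0.982 for the animal list, on the lower side, 0.00616 for ribosomal proteins and 0.000142 for cell cycle genes, and no filter gave 0.0226 and 0.0281 for these last lists. Leaving out 1 array gave 0.564 to 0.877 for the animal list and 0.148 to 0.877 for the cytoskeleton, both with a change of side, 0.0123 to 0.0552 for the respiratory chain, 0.0176 to 0.584 for ribosomal proteins, 0.0474 to 0.584 for cell cycle genes and 0.000563 to 0.584 for the egg envelope. Over all 16 alternatives the adjusted p lay between 5.54e-53 and 0.135 for germ plasm, 2.23e-33 and 0.126 for the vegetal cortex list, 3.19e-06 and 0.346 for the followed genes, 0.000381 and 0.225 for the respiratory chain, 0.00162 and 0.321 for localization factors and 0.0743 and 0.435 for Wnt and TGF-beta signalling.

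Some uncalled genes near 0 changed sign. Quantile normalization gave log2 changes of -0.23 for zfand4.L, -0.16 for ddx3x.L and -0.61 for ccnb1.S. Median centring gave 0.01 for pabpc1.L, 0.07 for zic2.S, 0.11 for rpl35a.S, 0.07 for rps18.L, 0.09 for rpl15.L, 0.03 for tubb4b.L, 0.11 for ccnb2.L, 0.10 for ccnb2.S and 0.02 for slc4a1.L; it moved the median of all tested probe sets from -0.20 to -0.07. Leaving out 1 array gave -0.02 to 0.02 for zfand4.L, -0.03 to 0.47 for ddx3x.L, -0.80 to 0.20 for pabpc1.S, -0.31 to 1.23 for sox3.L, -0.25 to 0.27 for ets2.L, -0.08 to 0.53 for zic2.L, -0.41 to 0.29 for zic2.S, -0.94 to 0.11 for uqcrc1.L, -0.36 to 0.33 for rpl35a.S, -0.17 to 0.06 for rps18.L, -0.16 to 0.07 for rpl15.L, -0.24 to 0.04 for tubb4b.L, -0.50 to 0.19 for actb.L, -0.11 to 0.21 for ccnb1.S, -0.20 to 0.16 for ccnb2.L, -0.21 to 0.15 for ccnb2.S, -0.20 to 0.91 for zpd.L, -0.57 to 0.99 for zpax.L, -0.72 to 0.50 for slc4a1.L and -0.26 to 0.86 for serpina1.S.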

Other observations

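The groups of genes and all tests in this part were chosen after the called genes were seen.

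The genes higher in the cortex included genes of lipid synthesis and storage. Of 27 tested genes chosen by symbol, 8 rose, and 4 of them, acsl1.L, acsl1.S, plin2.L and plin2.S, were already in the lists above. The others were acsbg2.L, elovl1.S, a fatty acid elongase gene (8.10-fold, log2 change 3.02 ± 0.53, adjusted p = 0.0191), dgat2.L, which makes triglyceride (6.54-fold, 2.71 ± 0.38, adjusted p = 0.00784), and cidec.L, a lipid droplet protein gene (3.38-fold, 1.76 ± 0.38, adjusted p = 0.0486). The median over the 27 genes was 0.06.

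Genes acting on poly(A) tails and on messenger RNA turnover were found as well, with 6 of 36 tested genes higher. They were tob2.L (10.2-fold, log2 change 3.34 ± 0.34), both homeologs of zfp36l2, which encodes a protein that binds AU-rich elements (7.99-fold for zfp36l2.S and 6.38-fold for zfp36l2.L), lsm14b.L, the poly(A) polymerase gene papola.L (6.02-fold, 2.59 ± 0.33) and the deadenylase gene parn.L (4.65-fold, 2.22 ± 0.32). Because both groups were drawn up with the called genes in view, these counts do not show that either group is more frequent than others. Over 70 families of at least 8 genes sharing a symbol stem, formed by rule, none passed in limma camera. The lowest adjusted p was 0.303, for tspan on the higher side and for nup on the lower side.

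Probe sets of homeologous copies were higher together more often than independent calls would give, and some pairs differed. Both members were tested for 636 pairs, and both rose in 9 pairs where 0.61 would be expected if L and S copies were called independently (Fisher's exact test, two-sided, p = 3.04e-10); in 23 pairs 1 member rose. The change differed between the members in 6 pairs by limma on the difference. For timm8b, the S copy rose while the L copy had a log2 change of -0.91, a difference of -5.86 ± 0.39 (L minus S, adjusted p = 0.000392), and for exd2 the difference was -3.53 ± 0.38 (adjusted p = 0.00665). The remaining pairs were ccni (-2.95), papola (3.07), rnf103 (2.73) and tmem38b (2.34). Probe sets of close homeologs can hybridize to both transcripts, which would hide such differences and would also make both copies pass together, so the joint count does not show that both transcripts rose. Each value rests on 1 probe set per copy.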
